A study of Mus musculus with 4 samples.

How the data were processed

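The renal capsule is the thin connective tissue sheath around the kidney. Single-cell RNA was sequenced from the capsules of young and aged mice, with 2 libraries per age and no treatment. Per the labels' protocols, capsules were removed from the kidneys and digested with a collagenase blend and DNase. The suspension was sieved, and libraries were made with a droplet 3' kit with unique molecular identifiers (UMIs). The ages, the strain and the number of mice behind each library are not given in the sources used here, so the 2 libraries of an age may be technical replicates. The p-values measure only the spread between these 4 libraries.

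The deposited matrices hold the count of UMIs per gene and barcode, as raw integers without normalization. Per the labels the authors made them with Cell Ranger 6.0.2 on mouse genome build GRCm38, while the file headers state version 6.0.1. The aligner's settings and the gene annotation are not given in the sources used here. Of the 52636 genes, 52403 (99.6%) had an identifier in GENCODE M21, which supplied the coordinates. A symbol carried by more than 1 identifier, as for 97 symbols, was kept as separate genes. Barcodes had already been called as cells by the authors. The libraries held 9712 and 10368 barcodes for the young replicates and 7067 and 12289 for the aged replicates, with 68052444, 70925446, 51180311 and 65118489 UMIs.

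Barcodes were kept with at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs. This kept 92.5% and 92.9% of the young barcodes and 95.7% and 97.4% of the aged barcodes. Barcodes with the highest simulated-doublet scores (Scrublet in scanpy 1.11.5) were removed, at a rate in proportion to the number of barcodes in the library, which took 698, 799, 382 and 1177 barcodes (7.77%, 8.29%, 5.65% and 9.83%). The cells used numbered 8290 and 8838 from the young and 6381 and 10796 from the aged libraries. Their median UMIs were 6963, 7056, 5924 and 4002, so aged replicate 2 was the shallowest per cell, and their median mitochondrial shares were 2.69%, 2.67%, 2.18% and 2.23%. Gene counts of the 2 replicates of an age varied more than counting error alone gives, with chi-square over degrees of freedom from 1.44 to 7.66 over the classes. A check for mixed-up libraries from sex-linked genes set apart 0 libraries.

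Counts were scaled to 10000 UMIs per cell and log-transformed. The 4 libraries were clustered together without integration, from 2000 variable genes, 30 principal components and 15 neighbours, by the Leiden method at resolution 1 (leidenalg 0.10.2, Python 3.11.15). Clusters were named from marker lists of 23 classes. A cluster whose leading genes belonged to another class, or were cell cycle genes, stayed unnamed. Names are given as "-like" because they rest on transcripts alone. The marker lists, the 37 gene lists, the rule for named genes and the tests were fixed before the data were examined.

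Gene changes with age were tested on UMI counts summed per library and class, in the 7 classes with at least 50 cells in each library. Type 2 innate lymphoid-like cells reached that number without having been listed by name beforehand. The tool was edgeR 4.0.16 (quasi-likelihood test, TMM scaling, its filter on low counts, R 4.3.3). P-values were adjusted by the Benjamini-Hochberg method, and a gene past an adjusted p of 0.05 is said to have risen or fallen in aged over young libraries. An exact permutation of 2 libraries against 2 cannot go below p = 0.333, so every p given comes from the edgeR or limma models. Levels are TMM-scaled counts relative to the class total of each library (CPM), as means ± SD over n = 2 libraries per age. The levels of Igkc, Kap, Adipoq and Car3, those of Col1a1, Ccl8 and Sparc where classes are set side by side, and those of whole libraries are CPM without TMM scaling. Shares of cells were tested by edgeR on the number of cells per class, over the 16 classes with at least 40 cells. Tests on simulated data showed that a large rise in abundant classes makes the shares of others fall and pass the threshold, so other denominators are given beside the shares. In the same kind of test 76% of 2-fold gene changes put into fibroblast-like sums and 24% of those put into B cell-like sums were called. Intervals and the limits allowed by a count of 0 (3 counts over the group) cover counting error only.

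The gene lists were tested in each class by camera (limma 3.58.1, preset correlation 0.01) where at least 5 members were measured. Adjustment was over all lists and classes together. Camera asks whether a list's members moved more than the other genes. It was run again with an estimated correlation, and fry was run beside it. With an estimated correlation camera has only the 2 residual degrees of freedom of the fit, and thus little power. A call lost there cannot tell correlation among a list's genes from that low power. The main p of fry tests whether a list's genes move, on balance, one way, and its mixed p whether they change in either direction. Neither compares the list with other genes. The lists covered collagen and other matrix, basement membrane, matrix proteases, myofibroblast genes, growth factors, interferon-stimulated genes, antigen presentation by MHC classes I and II, chemokines, NF-kB targets, complement, alarmins, senescence, cell cycle, immediate early genes, heat shock, unfolded protein response, oxidative stress, ribosomal proteins, nuclear-encoded oxidative phosphorylation, glycolysis, cholesterol and fatty acid metabolism, the clock, resident, lipid-associated, M1-type and M2-type macrophages, naive lymphocytes, effector and regulatory T cells, age-associated B cells, endothelial activation, immunoglobulin and tubule transcripts, haemoglobin and sex-linked genes. The haemoglobin and sex-linked lists were kept for checks and not tested with camera. The age effects of fibroblast-like and macrophage-like cells were compared by a class-by-age interaction in edgeR on 8 sums with library as a block.

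Genes were named by rule. In fibroblast-like and macrophage-like cells the rule took the 10 largest rises and the 10 largest falls, and in each other class 5 of each, among genes at 20 CPM or more whose libraries did not overlap between ages. It left out predicted genes, mitochondrial genes and genes at under 10% of their level in the class that holds most of them, since free RNA can bring those to any droplet. It added up to 4 members per list with the smallest adjusted p, and a set of genes with known roles in the capsule or in ageing. The text names a subset of these. Genes outside the rule are said to be chosen after their values were seen.

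The alternatives chosen at that time were DESeq2 1.42.0 size factors and test, no filter on low counts, doublets kept, a stricter cell filter (500 genes, 10% mitochondrial), Leiden resolutions 0.5 and 2, each library left out, the replicate number as a block, other denominators of the shares, and the lists without genes under the free RNA limit. Fits within single clusters, T-like cells joined with an unnamed cluster, macrophage-like cells joined with unnamed clusters, and dendritic cell-like cells without cluster 31 were added after the data were seen. The lists in the T cell-like clusters and without cluster 31 were adjusted apart from those in the other added fits. Where a library was left out, the lone library of its age was assumed to vary like the other age. Classes with fewer cells, and any read-level or variant data, were not analysed here.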

Results

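Lymphocytes and plasma cells made up larger shares of the cells recovered from the capsule of aged mice than of young mice, and aged fibroblast-like cells had less Col1a1 and Col3a1 transcript. Aged macrophage-like cells had more of the chemokine Ccl8 and of the lipid-sensing receptor Trem2, and less of the scavenger receptor Cd163. The series asks how the cells of the renal capsule differ between young and aged mice. The comparisons below cover the shares of the cell classes, the genes and gene lists of 7 classes, and the difference between fibroblast-like and macrophage-like cells. All values are aged over young, and ± is the SD over n = 2 libraries per age.

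Lymphocytes rose as a share of all cells. T cell-like cells went from 1.64 ± 0.363% to 19.75 ± 1.98% (log2 ratio 3.59, edgeR adjusted p = 0.0055), and B cell-like cells from 1.18 ± 0.203% to 8.49 ± 1.53% (2.84, adjusted p = 0.0062). Natural killer cell-like cells went from 0.515 ± 0.0729% to 1.92 ± 0.0974% (1.90, adjusted p = 0.0062), dendritic cell-like cells from 2.54 ± 0.33% to 6.29 ± 0.316% (1.31, adjusted p = 0.010) and monocyte-like cells from 0.65 ± 0.152% to 2.32 ± 0.0941% (1.83, adjusted p = 0.011). Plasma cell-like cells, which secrete antibody, made up 1.49 ± 0.415% of the aged cells. They were 0 of 17128 young cells, which allows a share of up to 0.0175%, so with doublets removed they were at least 84.8-fold higher in the aged libraries (adjusted p = 0.017). With doublets kept the class held 4 and 1 cells of the young libraries and the log2 ratio was 5.85 (adjusted p = 0.0049), which is below that bound.

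Fibroblast-like cells, the makers of the capsule's matrix, fell from 49.75 ± 0.0527% to 21.62 ± 0.318% (log2 ratio -1.20, adjusted p = 0.0055). Mesothelial-like cells, which line the outer surface, fell from 1.32 ± 0.00636% to 0.408 ± 6.98e-05% (-1.69, adjusted p = 0.0055). Proximal tubule-like cells, which come from the cortex under the capsule, fell from 3.89 ± 0.485% to 0.691 ± 0.424% (-2.46, adjusted p = 0.042), and loop and distal tubule-like cells from 0.32 ± 0.0433% to 0.0185 ± 0.0262% (-3.74, adjusted p = 0.041). Macrophage-like cells were 25.5 ± 0.403% and 21.3 ± 2.32% of all cells (log2 ratio -0.26, adjusted p = 0.17), while at Leiden resolution 2 their share fell (-0.65, adjusted p = 0.034). At that resolution a cluster of 1037 cells that scored best as macrophage stayed unnamed. It held 0.71% and 0.61% of the young and 5.8% and 5.13% of the aged libraries, so the fall depends on how clusters were named. Of immune cells alone macrophage-like cells fell from 75.2 ± 0.457% to 33.8 ± 2.96% (-1.15, adjusted p = 0.012), while T cell-like cells rose from 4.82 ± 1.02% to 31.4 ± 3.81%. On that denominator the share of dendritic cell-like cells did not pass the test (7.48 ± 0.899% and 9.98 ± 0.713%, log2 ratio 0.42, adjusted p = 0.20). Blood endothelial-like cells (2.73 ± 1.01% and 5.29 ± 1.18%, log2 ratio 0.96, adjusted p = 0.14, but 3.50 and adjusted p = 0.0071 at Leiden resolution 0.5), type 2 innate lymphoid-like cells (0.9 ± 0.297% and 0.961 ± 0.0954%, adjusted p = 0.82), mast cell-like cells (0.69 ± 0.737% and 0.159 ± 0.0413%, adjusted p = 0.23), mural cell-like cells (adjusted p = 0.63) and neutrophil-like cells (adjusted p = 0.85) did not pass it either. At resolution 0.5 the blood endothelial-like class left out an unnamed cluster of 605 cells that scored best as that class. It held 3.12% and 1.84% of the young and 1.07% and 1.07% of the aged libraries, so the higher ratio there depends on naming. In the reported fit unnamed clusters held 7.88 ± 0.75% of the young and 8.68 ± 0.0881% of the aged cells. The largest of them with T cell markers went from 0.986% to 5.68%, and counting it as T cell-like gave a log2 ratio of 3.28 (adjusted p = 0.0062).

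In all, 10 of 16 shares passed the test, 6 rising and 4 falling. Shares sum to a whole, so a rise in abundant classes lowers the others. Over non-tubular cells 8 of 14 shares passed. Without aged replicate 1, and likewise without aged replicate 2, only 2 shares passed, those of fibroblast-like and mesothelial-like cells, and T cell-like cells were then at adjusted p = 0.057 and 0.061. The fall of proximal tubule-like cells was also lost without young replicate 1 (adjusted p = 0.11) or young replicate 2 (adjusted p = 0.16). With doublets kept both tubule falls were lost (proximal adjusted p = 0.074, loop and distal 0.063). Their size also moved with the aged libraries. The proximal log2 ratio was -1.97 without aged replicate 1 and -3.31 without aged replicate 2. The loop and distal ratio was -3.07 and -7.66, from 0 and 4 cells in aged replicates 1 and 2. The log2 ratio of mast cell-like cells was -2.96 without young replicate 1 and -0.13 without young replicate 2. Young replicate 1 held 14 of these cells and young replicate 2 held 107, the latter with a median of only 873 UMIs. At Leiden resolution 2 the leading genes of the class included the haemoglobin genes Hbb-bs, Hbb-bt and Hba-a1. Its share thus rests on young replicate 2.

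**Figure D1:**
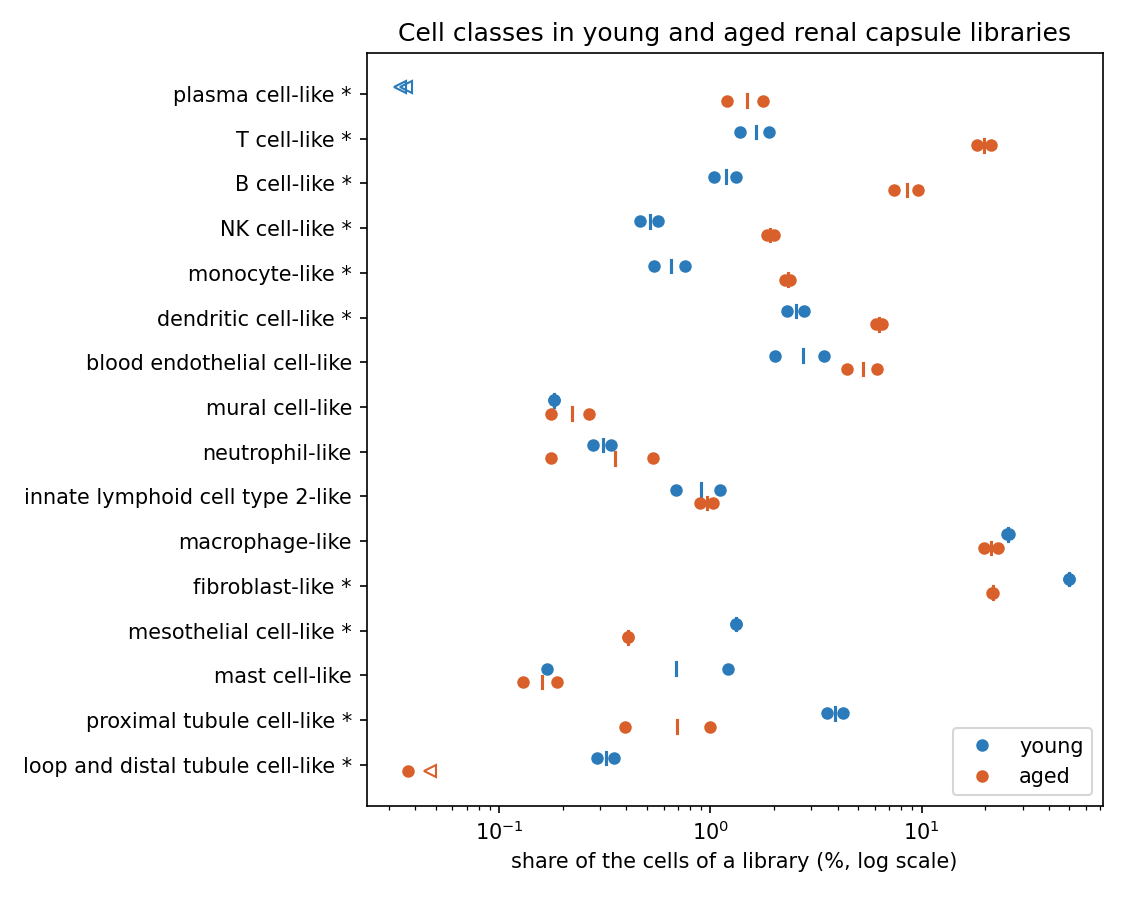
Share of each cell class among all cells used, in percent on a log axis, with 1 point per library and a line at the mean of each age. An asterisk marks classes with adjusted p under 0.05 by edgeR and an open triangle the limit that 0 cells allow, as for the plasma cell-like class, which has 0 young cells and 1.49% of the aged cells.

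In fibroblast-like cells 4531 of 15539 tested genes changed with age, 2195 rising and 2336 falling by edgeR, and 1305 of them changed more than 2-fold. The main collagens of the capsule fell together with other matrix genes. Col1a1, a chain of type I collagen (ENSMUSG00000001506, GRCm38 chromosome 11, 94936224 to 94953042, protein-coding), fell from 4396 ± 177 to 1107 ± 36.8 CPM (log2 fold change -1.99 ± 0.079 SE, adjusted p = 1.2e-13). Col3a1 fell from 6395 ± 85.6 to 1941 CPM (-1.72, adjusted p = 7.1e-13) and Sparc, a collagen-binding matrix protein, from 9909 ± 469 to 2377 ± 191 CPM (-2.06). Of the 29 fibrillar collagen and matrix genes 22 fell and 4 rose (22 and 4 adjusted over the list alone), with a median log2 fold change of -0.88 (camera adjusted p = 2.2e-13, adjusted p = 0.492 with an estimated correlation). This list alone also moved one way by fry (adjusted p = 0.0268). In the same libraries Col1a1 went from 37.7 to 4.91 CPM in macrophage-like and from 81.3 to 4.03 CPM in B cell-like droplets, classes that do not make it. Of the 17 basement membrane genes 12 fell, among them the laminin chain Lamc1 (605 to 296 CPM, -1.03), and 1 rose, with a median of -0.62 (camera adjusted p = 1.7e-07, adjusted p = 0.492 with an estimated correlation). The basement membrane collagen Col4a1 did not pass the test (394 and 405 CPM, 0.04, adjusted p = 0.75).

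Among the lists of immune signals, those of chemokines and of MHC class I rose in the same fibroblast-like cells (both at adjusted p = 0.492 with an estimated correlation) and that of complement did not pass. C4b, a complement component (ENSMUSG00000073418, chromosome 17, 34728380 to 34743882, protein-coding), rose from 92.2 ± 5.9 to 613 ± 6.43 CPM (log2 fold change 2.73, adjusted p = 2.0e-15). Cxcl12, a chemokine that holds lymphocytes and progenitors in their niches (ENSMUSG00000061353, chromosome 6, 117168535 to 117181367, protein-coding), rose from 138.5 ± 3.25 to 668 ± 10.7 CPM (2.27, adjusted p = 2.0e-14). Of 23 chemokines 11 rose and 5 fell (camera adjusted p = 0.0025, adjusted p = 0.492 with an estimated correlation), with Cxcl14 (15.3 to 89.7 CPM) and the eosinophil attractant Ccl11 (559 to 1134 CPM) among the rises. The matrix-degrading enzyme Mmp3 rose from 7.61 ± 0.73 to 80.8 ± 0.71 CPM (3.41, adjusted p = 3.2e-16), and the adhesion molecule Vcam1 from 53.0 to 141 CPM (1.42). Of 19 genes of MHC class I presentation 16 rose, such as H2-Q4 (25.2 to 68.0 CPM) and H2-M3 (45.6 to 80.2 CPM), and 1 fell (camera adjusted p = 7.1e-10, adjusted p = 0.492 with an estimated correlation). The alarmin Il33 fell (157 to 93.9 CPM, -0.74), and the complement component C3 did not pass the test (4909 and 4876 CPM, -0.01, adjusted p = 0.94). The complement list did not pass it either, with 3 genes up and 4 down of 21 (camera adjusted p = 0.68).

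The cell cycle inhibitor gene Cdkn2a, used as a mark of senescence, rose from 0.56 to 7.97 CPM (log2 fold change 3.81, adjusted p = 3.3e-10), Cdkn2c from 17.6 to 79.9 CPM (2.18) and Cdkn2b from 10.4 to 22.5 CPM (1.10), while Cdkn1a rose less (100 to 144 CPM, 0.53, adjusted p = 1.4e-04). The senescence list as a whole, with 9 of 18 members rising and 4 falling in fibroblast-like cells, did not pass (9 and 5 adjusted over the list alone, camera adjusted p = 0.096), and Igfbp3, one of its secreted members, fell (381 to 169 CPM, -1.18). The growth factor and Wnt or BMP list fell, with 18 of 29 members down (21 adjusted over the list alone) and 6 up (median -0.51, camera adjusted p = 1.4e-04, adjusted p = 0.492 with an estimated correlation). Bmp7 fell from 43.8 to 17.8 CPM (-1.30), and the hepatocyte growth factor gene Hgf rose from 1.5 to 9.46 CPM (2.65). The imprinted transcript H19, abundant in growing tissue, fell from 39.9 to 4.13 CPM (-3.29), and Itm2a from 190 to 21.7 CPM (-3.12). The lipid transfer protein gene Pltp rose from 43.6 to 250 CPM (2.52) and Gpnmb from 24.0 to 92.6 CPM (1.95). The metallothionein Mt1, a metal-binding stress protein, rose from 752 to 1551 CPM (1.04).

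Protein-folding genes fell in fibroblast-like cells. Of 20 genes of the unfolded protein response 12 fell and 0 rose, such as the endoplasmic reticulum chaperones Hspa5 (1199 to 748 CPM, -0.68) and Calr (817 to 612 CPM, -0.42), with a median of -0.31 (camera adjusted p = 1.7e-04, adjusted p = 0.504 with an estimated correlation). Of 16 heat shock genes 8 fell and 0 rose (adjusted p = 0.0069, or 0.058 without aged replicate 2, adjusted p = 0.653 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes rose, 16 of 35 with 0 falling (median 0.19, camera adjusted p = 5.3e-06, adjusted p = 0.563 with an estimated correlation), for example Cox8a (557 to 769 CPM, 0.47). The mitochondrially encoded genes mt-Nd1 (-0.52), mt-Nd2 (-0.69), mt-Nd3 (-1.53) and mt-Nd4 (-0.76), chosen after their values were seen, fell. Ribosomal protein genes rose, 27 of 47 with 1 falling (median 0.27, adjusted p = 1.3e-07, adjusted p = 0.492 with an estimated correlation), for example Rps19 (1194 to 1738 CPM, 0.54). Cholesterol synthesis genes, 5 of 19 (adjusted p = 0.0066, or 0.16 without aged replicate 1), oxidative stress genes, 7 of 20 with 3 falling (adjusted p = 0.015), and MHC class II genes, 5 of 12, moved up as lists. These 3 were lost with an estimated correlation (adjusted p = 0.564, 0.505 and 0.504). The MHC class II call in fibroblast-like cells (adjusted p = 0.010) was lost without young replicate 1 (0.054) or aged replicate 2 (0.088). The cell cycle list fell with 9 of 26 members (adjusted p = 0.010) and was lost without young replicate 1 (0.10), aged replicate 2 (0.089) or the genes under the free RNA limit (0.56) and it was at adjusted p = 0.492 with an estimated correlation. All 19 list calls of this class were lost with an estimated correlation (adjusted p = 0.492 to 0.653 with an estimated correlation).

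Transcripts of plasma cells, lymphocytes and tubule cells moved in the fibroblast-like droplets in the same direction as those cells' shares or library totals. Igkc, an immunoglobulin chain chosen after its values were seen, rose from 4.07 to 209 CPM in fibroblast-like droplets (adjusted p = 0.042, or 0.35 without young replicate 1 and 0.33 without young replicate 2) and stood at 4.7 and 213 CPM in macrophage-like droplets (adjusted p = 0.070), against 553320 CPM in plasma cell-like cells. In fibroblast-like droplets 8 of 9 immunoglobulin genes, 8 of 18 effector T cell genes and 5 of 9 naive lymphocyte genes rose. These 3 list calls were lost with an estimated correlation (adjusted p = 0.492, 0.504 and 0.492). The lipid-associated macrophage list rose there, with 9 of 17 members (adjusted p = 2.3e-04, adjusted p = 0.492 with an estimated correlation), including Apoe (815 to 2247 CPM, 1.46), which stood at 8.1% of its macrophage-like level. That call was lost without the genes under the free RNA limit (adjusted p = 0.13). The share of macrophage-like cells did not rise, so this list did not follow a share. The same list also rose in macrophage-like cells, so free RNA from them remains a possible source. Of the 18 tubule transcripts 10 fell (adjusted p = 5.5e-05, adjusted p = 0.563 with an estimated correlation), and Kap, a proximal tubule transcript, stood at 46.9 and 11.03 CPM (adjusted p = 0.28). M2-type genes, most of them macrophage transcripts, fell with 5 of 9 members (adjusted p = 0.015, adjusted p = 0.504 with an estimated correlation).

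Different clusters held most fibroblast-like cells in the 2 ages. Clusters 1, 2, 3 and 7 held 26.9%, 24.1%, 24.98% and 18.6% of the young class, and clusters 5 and 9 held 51.5% and 32.7% of the aged class. Fits within single clusters were run for clusters 2 and 3, which had 50 cells in every library. Cluster 5 also had 50 cells in every library but was not fitted alone. Within clusters 2 and 3, 751 and 378 genes changed. Col1a1 fell in both (log2 fold change -1.95 and -1.77), as did Col3a1 (-2.38 and -1.87), while C4b (2.41 and 1.31), Cxcl12 (2.29 and 1.12), Pltp (2.39 and 2.64) and Cdkn2c (1.24 and 1.54) rose in both. Ccl11 passed the test in neither (0.50 and 0.19), Il33 in neither (-0.13 and 0.19), Cdkn2b in neither (0.92 and 0.92), and Cxcl14 rose in cluster 2 only (4.06 and 0.19). Mmp3 rose in cluster 3 (1.12) and was at 1.44 (adjusted p = 0.55) in cluster 2. The calls of Cdkn1a and Cox8a were lost in both, those of Hspa5, Calr, H2-Q4 and Rps19 in cluster 2, and those of Vcam1, Igfbp3, Mt1, H2-M3 and Hgf in cluster 3. The differences between the clusters were not tested.

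**Figure D2:**
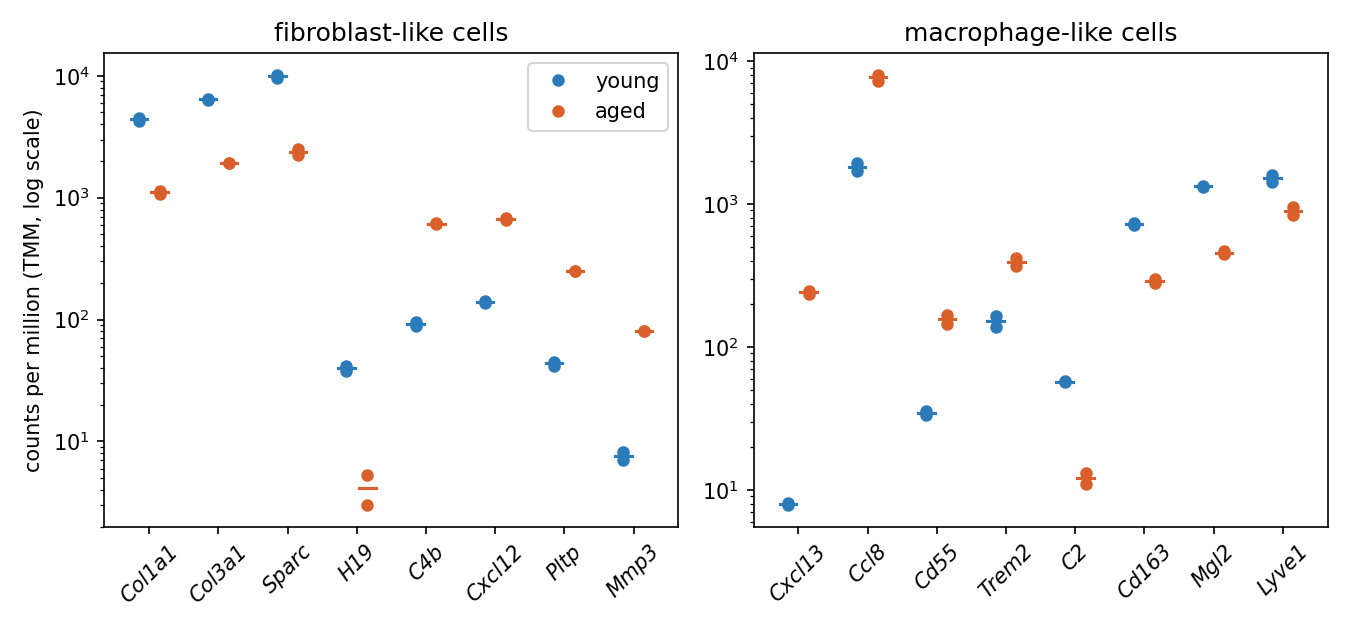
Levels of selected genes in fibroblast-like and macrophage-like cells, in CPM on a log axis, with 1 point per library and a line at the mean of each age. Both aged libraries lie below both young libraries for Col1a1 in fibroblast-like cells and for Cd163 in macrophage-like cells, and above them for C4b and for Ccl8.

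In macrophage-like cells 2233 of 13339 tested genes changed, 1096 rising and 1137 falling, and 720 of them more than 2-fold. Cxcl13, which draws B cells (ENSMUSG00000023078, chromosome 5, 95956951 to 95961068, protein-coding), rose from 7.94 ± 0.18 to 240.4 ± 10.0 CPM (log2 fold change 4.92, adjusted p = 1.7e-30), and Ccl8, a monocyte attractant (chromosome 11, 82115185 to 82116799), from 1815 ± 168 to 7672 ± 523 CPM (2.08, adjusted p = 4.1e-19). The chemokine list had no common direction, with 5 members up and 6 down of 22 (median -0.01, mean 0.50, camera adjusted p = 0.50), and the receptor Ccr1 fell from 127 to 48.2 CPM (-1.40). The Cxcl13 call was lost at Leiden resolution 0.5 (2.61, adjusted p = 0.36), with unnamed clusters 15 and 29 counted in (2.71, 0.34), within cluster 6 (5.81, 0.17) and within cluster 11 (6.73, 0.37), the highest adjusted p of its alternatives. It passed within cluster 0 (4.56, 1.1e-06).

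The list of lipid-associated macrophage genes, a state described in fat and injured tissue, rose (adjusted p = 2.8e-07, adjusted p = 0.492 with an estimated correlation). Trem2, the lipid-sensing receptor of that state (chromosome 17, 48346401 to 48354147), rose from 151 ± 17.8 to 394 ± 36.6 CPM (log2 fold change 1.39, adjusted p = 3.0e-14), Lgals3 from 255 to 538 CPM (1.08), the lysosomal membrane gene Cd63 from 475 to 914 CPM (0.94) and the protease gene Ctsd from 1330 to 2186 CPM (0.72). Of 19 members 8 rose and 1 fell (9 and 2 adjusted over the list alone), with a median of 0.38. The lipoprotein gene Apoe, which macrophage-like cells carry at high level, did not pass the test (26200 and 27860 CPM, 0.09, adjusted p = 0.62). The list rose within each of the 3 macrophage-like clusters (median 0.11, 0.63 and 0.55).

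Markers of resident macrophages moved apart. The haemoglobin scavenger receptor Cd163 (chromosome 6, 124304656 to 124330527) fell from 726.5 ± 19.1 to 287 ± 13.3 CPM (log2 fold change -1.34, adjusted p = 4.2e-15), the lectin Mgl2 from 1326 to 456 CPM (-1.54), the hyaluronan receptor Lyve1 from 1515 to 890 CPM (-0.77), the phosphatidylserine receptor Timd4 from 301 to 192 CPM (-0.65) and Retnla from 15550 to 9366 CPM (-0.73). The folate receptor Folr2 fell from 2793 to 2247 CPM (-0.31, adjusted p = 0.015), a call lost without young replicate 1 (0.071), young replicate 2 (0.25) or aged replicate 2 (0.053). The mannose receptor Mrc1 did not pass the test (2224 and 2228 CPM, 0.00, adjusted p = 0.99), and the lectin Cd209a (48.4 to 168 CPM, 1.80), the complement receptor Vsig4 (21.9 to 74.5 CPM, 1.76) and the complement regulator Cd55 (34.5 to 156 CPM, 2.18) rose. The resident macrophage list (4 up and 6 down of 19, median -0.13, mean 0.02, adjusted p = 0.64), the M2-type list (4 up and 4 down of 10, median 0.03, mean -0.09, adjusted p = 0.76) and the M1-type list (1 up and 3 down of 10, adjusted p = 0.15) did not pass. The complement gene C2 fell from 57.2 to 12.1 CPM (-2.25), at 6.2% of its mesothelial-like level. Clusters 0, 6 and 11 held 62.2%, 26.3% and 11.5% of the class in young and 60.3%, 24.3% and 15.5% in aged libraries, and within each Ccl8 rose (2.15, 2.02 and 2.21) and Cd163 fell (-1.30, -1.34 and -1.43).

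Interferon-stimulated genes fell in macrophage-like cells. Of 40 members 10 fell and 1 rose (17 and 1 adjusted over the list alone), such as Rsad2 (99.4 to 58.2 CPM, -0.77) and Oasl2 (122 to 83.7 CPM, -0.54), both antiviral effectors, with a median of -0.24 (camera adjusted p = 1.3e-07, adjusted p = 0.504 with an estimated correlation). Heat shock genes fell with 4 of 16 members (adjusted p = 1.4e-05, adjusted p = 0.504 with an estimated correlation) and cell cycle genes with 8 of 22 (adjusted p = 3.7e-05, adjusted p = 0.492 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes rose with 13 of 35 members (median 0.20, adjusted p = 1.3e-06), ribosomal protein genes with 12 of 47 (adjusted p = 4.2e-05) and oxidative stress genes with 3 of 20 (adjusted p = 0.0020, or 0.087 without young replicate 1 and 0.051 without aged replicate 1). These 3 were lost with an estimated correlation (adjusted p = 0.564, 0.522 and 0.492). The mitochondrially encoded mt-Nd1 (-0.51), mt-Nd2 (-0.76), mt-Nd3 (-1.34) and mt-Nd4 (-0.54) fell. Cholesterol synthesis genes rose with 4 of 19 members in macrophage-like cells (adjusted p = 0.019, or 0.18 without young replicate 2 and 0.32 without aged replicate 2, adjusted p = 0.639 with an estimated correlation). MHC class II genes rose with 4 of 14 members (adjusted p = 0.039, or 0.42 without young replicate 2 and 0.65 without aged replicate 2, adjusted p = 0.695 with an estimated correlation), while the invariant chain Cd74 did not pass the test (7658 and 8503 CPM, 0.15, adjusted p = 0.35). Cdkn2a rose from 1.79 to 13.4 CPM (2.91) and the clock repressor Nr1d1 from 3.32 to 16.3 CPM (2.30). The clock list (6 up and 5 down of 15, adjusted p = 0.38) and the senescence list (3 up and 4 down of 17, adjusted p = 0.21) did not pass. The lists of other cells moved as in the fibroblast-like droplets: 24 of 29 collagen and matrix genes, 12 of 14 basement membrane genes and 4 of 18 tubule transcripts fell, and 6 of 9 immunoglobulin genes and 3 of 12 effector T cell genes rose. These 5 were lost with an estimated correlation (adjusted p = 0.492, 0.492, 0.548, 0.492 and 0.504). The growth factor list fell with 7 of 16 members (adjusted p = 0.023) and lost its call without any 1 of the libraries (adjusted p = 0.24, 0.12, 0.21 and 0.082 without young replicates 1 and 2 and aged replicates 1 and 2), and it was at adjusted p = 0.492 with an estimated correlation. The 15 list calls of this class were lost with an estimated correlation (adjusted p = 0.492 to 0.695 with an estimated correlation). Without young replicate 1 or young replicate 2 the genes that changed numbered 1206 and 1291.

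The age effects of fibroblast-like and macrophage-like cells differed for 2731 of 15791 genes by the interaction test, and for 12 of 35 lists. MHC class I genes rose in fibroblast-like cells and had 0 of 19 members changed in macrophage-like cells (median difference 0.40, fibroblast minus macrophage, camera adjusted p = 6.8e-13, adjusted p = 0.474 with an estimated correlation). The interferon-stimulated list differed as well (median difference 0.26, adjusted p = 1.2e-05, adjusted p = 0.474 with an estimated correlation). In fibroblast-like cells 5 of its 40 members rose and 4 fell (adjusted p = 0.73). The unfolded protein response differed too (median difference -0.32, adjusted p = 3.3e-09, adjusted p = 0.474 with an estimated correlation), with Hspa5 at -0.67. In macrophage-like cells that list did not pass (2 up and 2 down of 20, adjusted p = 0.99). Among genes, C4b (2.10), Cxcl12 (2.27), Pltp (2.48) and Apoe (1.32) had the higher log2 fold change in fibroblast-like cells, and Cd55 (-2.42) and Cxcl13 (-5.05) in macrophage-like cells. Cdkn2a (0.85, adjusted p = 0.10), Ccl8 (-0.18, adjusted p = 0.30) and Trem2 (-0.64, adjusted p = 0.074) did not pass the interaction test. All 12 list calls were lost with an estimated correlation (adjusted p = 0.474 to 0.595 with an estimated correlation). The genes that differed numbered 1783 without young replicate 2 and 1623 without aged replicate 1.

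**Figure D3:**
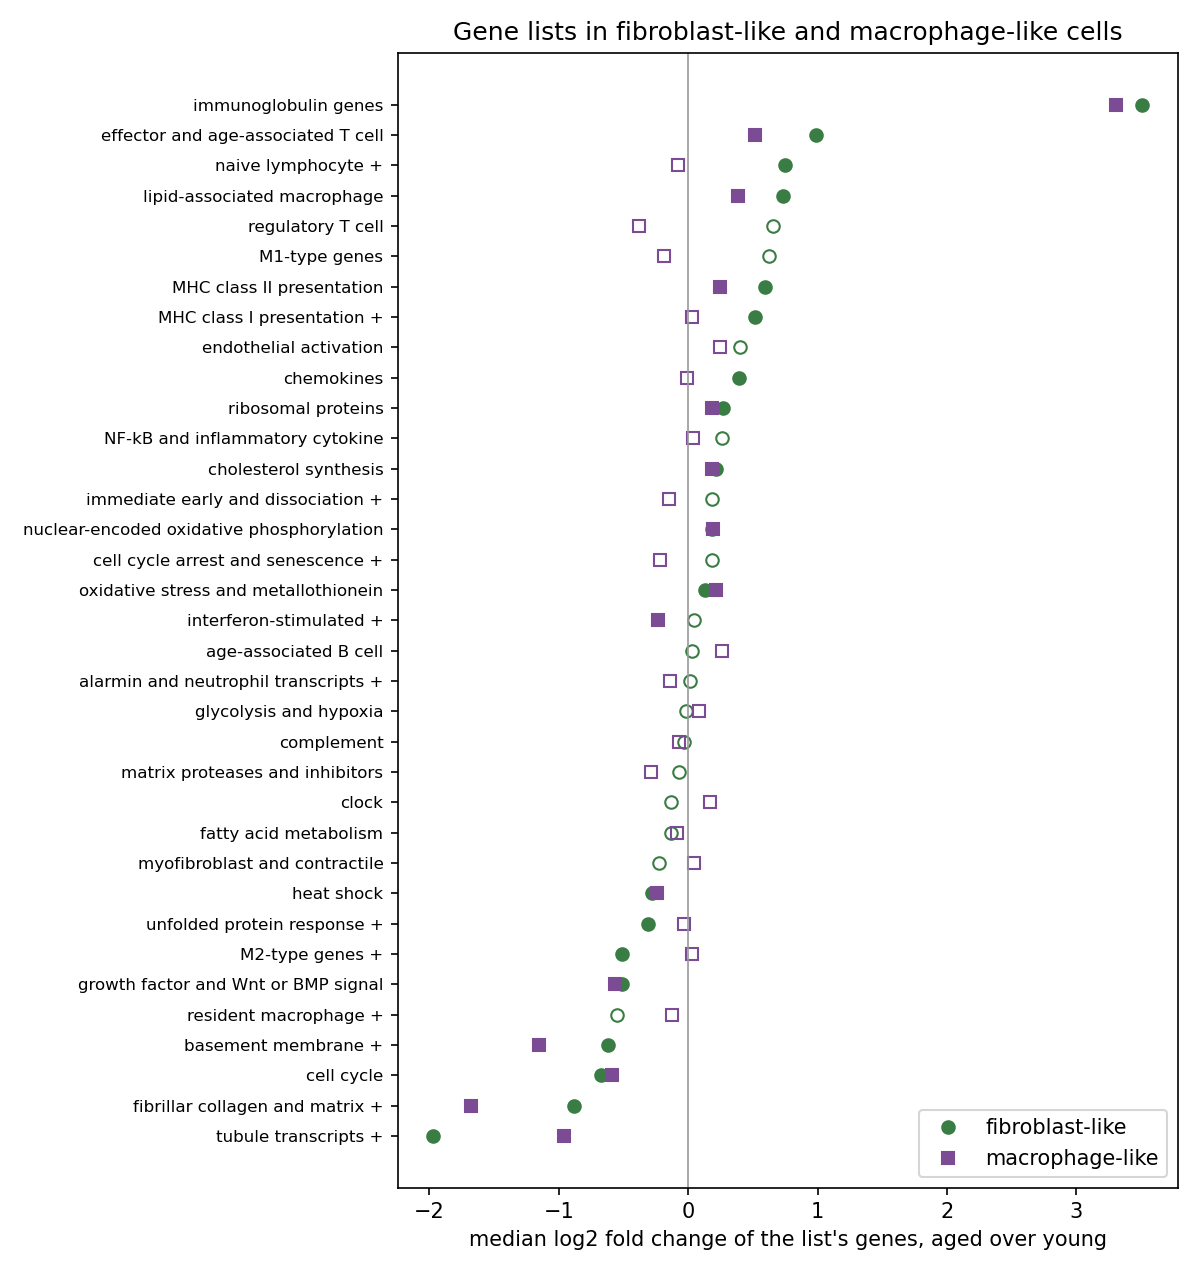
Median log2 fold change, aged over young, of the members of each gene list in fibroblast-like and in macrophage-like cells. Filled points mark lists past adjusted p = 0.05 by camera, and a plus sign marks lists that differed between these classes. The collagen and matrix list is filled and below 0 in fibroblast-like and in macrophage-like cells.

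In blood endothelial-like cells 1818 of 9876 tested genes changed, 839 rising and 979 falling. The endothelial activation list rose and the fatty acid metabolism list fell over the class, both at adjusted p = 0.492 with an estimated correlation. Plvap, the protein of endothelial fenestrae, rose from 419 to 3577 CPM (log2 fold change 3.09), the adhesion molecule Vcam1 from 12.8 to 127 CPM (3.22), the tip cell gene Esm1 from 175 to 1136 CPM (2.71), Igfbp3 from 559 to 2165 CPM (1.95) and Il33 from 16.6 to 94.4 CPM (2.53). The fatty acid carriers Fabp4 (41120 to 12485 CPM, -1.72) and Cd36 (3287 to 1144 CPM, -1.52), the fatty acid synthase Fasn (111 to 11.03 CPM, -3.28), the adipogenic regulator Pparg (244 to 49.2 CPM, -2.33) and the fat cell genes Cfd (888 to 81.1 CPM, -3.49) and Adig (100 to 3.69 CPM, -4.77) fell. Of 14 endothelial activation genes 9 rose and 1 fell (camera adjusted p = 1.1e-07, adjusted p = 0.492 with an estimated correlation), and of 20 fatty acid metabolism genes 13 fell and 0 rose (adjusted p = 1.4e-11, adjusted p = 0.492 with an estimated correlation). Different clusters held most of the class in the 2 ages, cluster 16 with 85.2% of the young cells and cluster 14 with 83.6% of the aged cells. Within them 90 genes changed in cluster 14 and 162 in cluster 16. Cluster 14 had only 38 and 29 young cells, under the 50 per library asked of a class. At Leiden resolution 0.5 the named class had the same cells per library as cluster 14. Plvap rose in cluster 14 (0.60) and Vcam1 too (2.27), but Esm1 (0.17 and -0.16), Igfbp3 (-0.19 and -0.22), Fabp4 (-0.18 and -0.08) and Pparg (-0.27 and -0.32) passed the test in neither, and Fasn (-2.21), Cfd (-1.37) and Adig (-2.75) fell in cluster 16. The endothelial activation list did not pass in cluster 14 (median -0.07, adjusted p = 0.63) or cluster 16 (0.38, adjusted p = 0.081). The fatty acid metabolism list fell in cluster 16 (-0.59, adjusted p = 1.0e-04) and did not pass in cluster 14 (adjusted p = 0.42). Fat cell markers were lower in the same aged droplets, Adipoq at 454 and 11.2 CPM (adjusted p = 0.12) and Car3 at 6018 and 106 CPM (adjusted p = 0.095), and cluster 16 scored second as adipocyte (3.58). How much of the lipid change lies in endothelial cells themselves was not tested.

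Other lists moved in the blood endothelial-like class with the same limit. MHC class I genes rose with 7 of 19 members (adjusted p = 2.1e-04, adjusted p = 0.492 with an estimated correlation), for example H2-T23 (305 to 642 CPM, 1.07) and H2-D1 (2249 to 3474 CPM, 0.63), whose calls were lost in cluster 14 (log2 fold change 0.42 and 0.25) and that of H2-T23 also in cluster 16 (0.31), and MHC class II genes with 7 of 8 (adjusted p = 5.1e-06). NF-kB targets rose with 6 of 15 (adjusted p = 5.2e-04). The MHC class II and NF-kB calls were each at adjusted p = 0.492 with an estimated correlation. In cluster 14 alone the MHC class II list (median 1.79, adjusted p = 4.2e-08) and the NF-kB list (0.42, adjusted p = 8.7e-04) rose. Nuclear-encoded oxidative phosphorylation fell with 17 of 35 members (adjusted p = 1.3e-08, adjusted p = 0.571 with an estimated correlation), in contrast to its rise in fibroblast-like cells, a difference that was not tested. Heat shock, complement, basement membrane, collagen, myofibroblast, cell cycle, tubule and lipid-associated lists fell, and the effector T cell, alarmin and resident macrophage lists rose (camera adjusted p = 1.4e-11 to 0.047, adjusted p = 0.492 to 0.7 with an estimated correlation). Transcripts of other cells were also higher in these aged droplets. Without TMM scaling Cd3e went from 0.54 to 5.16 CPM, Ccl8 from 16.2 to 64.5 CPM and Igkc from 19.65 to 396 CPM. Free RNA can bring such levels, so the T cell and macrophage lists need not reflect endothelial cells. The genes that changed numbered 1171 without aged replicate 2 and 90 at Leiden resolution 0.5.

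In T cell-like cells 401 of 9916 tested genes changed, 211 rising and 190 falling, and the list of cytotoxic and age-associated effector T cell genes rose (adjusted p = 0.492 with an estimated correlation). Gzmk, a granzyme of memory CD8 T cells (chromosome 13, 113171608 to 113225908), rose from 64.5 ± 22.3 to 344 ± 15.0 CPM (log2 fold change 2.44, adjusted p = 6.3e-16), the transcription factor Eomes from 14.3 to 121 CPM (2.99), and the chemokines Ccl5 from 4066 to 11040 CPM (1.44) and Ccl4 from 192 to 911 CPM (2.23). Of the 25 effector genes 10 rose and 1 fell (15 and 3 adjusted over the list alone), with a median of 1.07 (camera adjusted p = 3.4e-07, adjusted p = 0.492 with an estimated correlation). Cd8b1 rose from 344 to 624 CPM (0.87) and Cd8a from 199 to 341 CPM (0.77, adjusted p = 9.6e-04, or 0.074 without aged replicate 2). Cd4 fell from 120 to 71.9 CPM (-0.76, adjusted p = 0.0095, or 0.40 without young replicate 1 and 0.28 without aged replicate 2), and the purine receptor P2rx7 from 99.8 to 28.2 CPM (-1.80). Ier3 rose from 6.83 to 260 CPM (5.21) and the interleukin 7 receptor Il7r from 445 to 740 CPM (0.74, adjusted p = 7.8e-04, or 0.056 without aged replicate 1 and 0.079 without aged replicate 2). The checkpoint receptor Pdcd1 (53.7 and 82.4 CPM, 0.68, adjusted p = 0.11) and Foxp3 (26.5 and 22.03 CPM, -0.30, adjusted p = 0.73) did not pass the test, nor did the regulatory T cell list (2 up and 1 down of 12, adjusted p = 0.67) and the naive lymphocyte list (2 up and 0 down of 11, median -0.13, mean 0.20, adjusted p = 0.86). Chemokines rose with 6 of 15 members (adjusted p = 0.0025, adjusted p = 0.492 with an estimated correlation) and ribosomal protein genes with 18 of 47 (median 0.41, adjusted p = 1.6e-16, adjusted p = 0.504 with an estimated correlation). With the unnamed cluster that carries T cell markers counted in, the granzyme Gzmm turned from a fall (-2.01, adjusted p = 1.1e-04, or 0.096 without young replicate 2, 0.12 without aged replicate 1 and 0.13 without aged replicate 2) to a rise (1.48), the naive lymphocyte list fell (median -0.45, adjusted p = 0.0019) and Gzmk stayed up (2.64). The class sat in different clusters in the 2 ages. Cluster 4, led by Gzmk, Ccl5 and Cd8a, held 28.4% of the young and 62.5% of the aged class, and cluster 12, led by Tnfrsf4, with Ctla4 and Cd4, 57.2% and 25.9%. Within cluster 4, with 43 and 36 young cells, the effector list (median 0.74, adjusted p = 1.3e-04), Gzmk (1.79), Eomes (2.17), Ccl4 (1.21), Ccl5 (0.89), Ier3 (6.70), Il7r (1.26) and Pdcd1 (2.04) rose. Cd8a (-0.08), Cd8b1 (-0.08), Cd4 (1.85) and P2rx7 (-1.26) did not pass there. Within cluster 12 Ccl4 (2.70), Il7r (1.13) and the regulatory T cell list (median 0.74, adjusted p = 3.6e-05) rose, P2rx7 fell (-1.36), and the effector list (adjusted p = 0.68), Gzmk (0.90), Ccl5 (-0.46), Ier3 (1.46), Cd4 (-0.07), Cd8a (-1.59) and Cd8b1 (0.13) did not pass. The changes of Cd4, Cd8a and Cd8b1 over the class thus passed within neither cluster. The changed genes numbered 181 without young replicate 1, 135 without aged replicate 1 and 111 without aged replicate 2.

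In B cell-like cells 164 of 8050 tested genes changed, 62 rising and 102 falling. Genes of naive lymphocytes fell, among them the chromatin organizer Satb1 (150 to 55.4 CPM, log2 fold change -1.39, adjusted p = 0.0063). The list had 2 of 7 members down (6 adjusted over the list alone) and a median of -0.86 (camera adjusted p = 3.5e-06, adjusted p = 0.492 with an estimated correlation). The age-associated B cell list rose with 1 of 8 members, Fcrl5 (12.3 to 52.9 CPM, 2.13, adjusted p = 0.032), or 4 adjusted over the list alone (camera adjusted p = 3.7e-05, adjusted p = 0.492 with an estimated correlation). The constant region Ighd, expressed on naive B cells, fell (881 to 523 CPM, -0.75, adjusted p = 0.025), the secretory chaperone Mzb1 rose (601 to 1029 CPM, 0.77, adjusted p = 0.028) and Ighm did not pass the test (3349 and 3626 CPM, 0.11, adjusted p = 0.80). The immunoglobulin list did not pass either (2 up and 1 down of 11, adjusted p = 0.070). Psmb9, a subunit of the immunoproteasome, rose from 160 to 314 CPM (0.95), and the immediate early gene Fos fell from 1316 to 761 CPM (-0.80). These gene calls were fragile. The changed genes numbered 12 without young replicate 1 and 1 without young replicate 2, and without those libraries the calls of Satb1 (adjusted p = 0.45 and 0.091), Fcrl5 (0.45 and 0.35), Ighd (0.45 and 0.18) and Mzb1 (0.44 and 0.18) were lost. The same held for Psmb9 (0.38 and 0.17) and Fos (0.085 and 0.36). Calls were also lost without aged replicate 1 for Ighd, Mzb1 (0.19 for both), Fos (0.13) and Fcrl5 (0.18), and without aged replicate 2 for Ighd (0.12), Mzb1 (0.074) and Fos (0.099).

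In dendritic cell-like cells 236 of 9875 tested genes changed, 114 rising and 122 falling. MHC class II genes rose, 4 of 15 with 0 falling (median 0.22, camera adjusted p = 2.3e-06, adjusted p = 0.492 with an estimated correlation), for example H2-Oa (164 to 243 CPM, log2 fold change 0.57, adjusted p = 0.016, or 0.14 without young replicate 1 and 0.16 without aged replicate 2) and H2-Eb2 (4.64 to 17.7 CPM, 1.89). Fscn1, an actin bundler of mature dendritic cells, rose from 37.1 to 84.0 CPM (1.15, adjusted p = 0.013), Apol7c from 36.2 to 88.4 CPM (1.27) and Zmynd15 from 13.4 to 48.2 CPM (1.80). All 3 are leading genes of cluster 31, which held 5.11 ± 4.46% of the young class, with 4 cells in young replicate 2, and 9.37 ± 0.829% of the aged class. Without that cluster the calls of Apol7c (-2.03, adjusted p = 0.72) and Zmynd15 (1.07, adjusted p = 0.33) were lost and Fscn1 did not reach the filter on low counts, while 243 genes changed. The lysozyme Lyz1 fell from 58.7 to 16.4 CPM (-1.84, a call lost with doublets kept or the stricter cell filter, adjusted p = 0.32 and 0.24) and the chaperone Hspa1a from 517 to 221 CPM (-1.22), with 3 of 15 heat shock genes down (adjusted p = 4.4e-06, adjusted p = 0.492 with an estimated correlation). Ribosomal protein genes rose with 17 of 47 members (adjusted p = 1.8e-21, adjusted p = 0.492 with an estimated correlation), for example Rps7 (1709 to 2601 CPM, 0.61). Resident macrophage genes, at low level in this class, fell with 7 of 19 members (adjusted p = 1.7e-05), cell cycle genes with 3 of 22 (adjusted p = 1.9e-04) and interferon-stimulated genes with 2 of 37 (adjusted p = 0.0015, or 0.22 without young replicate 1). These 3 were lost with an estimated correlation (adjusted p = 0.492, 0.492 and 0.504). In type 2 innate lymphoid-like cells 125 of 3395 tested genes changed, 46 rising and 79 falling. Calca, which encodes calcitonin gene-related peptide (chromosome 7, 114631478 to 114636357), rose from 70.0 to 332 CPM (2.25) and the sulfotransferase Hs3st1 from 24.6 to 168 CPM (2.68). The cytokine Il6 rose from 9.1 to 57.6 CPM (2.69, adjusted p = 0.030, or 0.29 without young replicate 1), and arginase, Arg1, fell from 586 to 165 CPM (-1.82). Immediate early genes rose with 5 of 21 members (adjusted p = 3.0e-05, adjusted p = 0.492 with an estimated correlation), among them Ier2 (1134 to 2189 CPM, 0.96) and Egr1 (316 to 662 CPM, 1.05). The alarmin list fell with 3 of 5 members (adjusted p = 3.1e-08, adjusted p = 0.492 with an estimated correlation), the calcium-binding genes S100a6 (2042 to 918 CPM, -1.15) and S100a10 (1923 to 1111 CPM, -0.78, adjusted p = 1.7e-04, or 0.16 without aged replicate 1) among them. The changed genes of this class numbered 67 without young replicate 1 and 49 without aged replicate 2.

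Across the 7 classes 98 of 212 list tests passed. With an estimated correlation 0 of the 98 calls passed (adjusted p = 0.492 to 0.748 with an estimated correlation). That rerun has only 2 residual degrees of freedom, so these losses cannot decide whether correlation among genes accounts for the calls. Collagen and matrix and tubule lists fell in 6 of 6 classes tested, basement membrane in 5 of 5 and cell cycle in 5 of 6. Clusters led by cell cycle genes stayed unnamed, so the cell cycle falls leave out their cells. Of these, the cluster scoring best as macrophage held 1.18% of the young and 0.645% of the aged cells. The cluster scoring best as dendritic cell went the other way, with 0.123% and 0.245%. In immune classes the matrix and tubule lists hold transcripts at the level of free RNA, such as Col1a1 at 37.7 to 4.91 CPM in macrophage-like and 56.9 to 5.02 CPM in T cell-like droplets against 4382 CPM in young fibroblast-like cells. MHC class II rose in 6 of 7, MHC class I in 5 of 7, ribosomal proteins in 6 of 7, nuclear-encoded oxidative phosphorylation in 5 of 7 with a fall in 1, and heat shock fell in 4 of 7. The shares of B cell-like and dendritic cell-like cells, which carry MHC class II transcripts, rose. Free RNA from them can reach other droplets, and how much of the MHC class II rises it accounts for was not tested. The mitochondrially encoded mt-Nd2 and mt-Nd3 fell in 7 of 7. Matrix proteases fell in 2 of 5, cholesterol synthesis rose in 3 of 6 and fell in 1, M2-type genes fell in 3 of 6 and fatty acid metabolism in 1 of 7. The lists for senescence and for glycolysis passed in 0 of 7 classes, the clock in 0 of 6, regulatory T cells in 0 of 5 and M1-type genes in 0 of 3. The shared genes included Ccl8, up in 5 classes, although in 4 of them it reached only 51.4 to 75.6 CPM in aged libraries against 7622 CPM in macrophage-like cells, a level that free RNA can bring. By fry the collagen and matrix list in fibroblast-like cells passed (adjusted p = 0.0268), and the lowest adjusted p of any other list and class was 0.0625. Where a list passed, its median, mean and test had the same sign. In each class every gene past the threshold had libraries that did not overlap between the ages. Of all tested genes 64.6% in fibroblast-like and 56.9% in macrophage-like cells did not overlap, against 33.3% by chance.

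A block of neighbouring genes on chromosome 1 rose in several classes. Of 11 tested genes between 84935134 and 85576899 (GRCm38), 10 rose in fibroblast-like cells (median log2 fold change 5.20), while of 11 flanking genes 4 rose and 1 fell. In macrophage-like cells 8 of 8 block genes rose (median 3.14), in B cell-like cells 4 of 7 and in dendritic cell-like cells 2 of 4. C130026I21Rik, a member outside the naming rule that was chosen after its values were seen, rose from 0.8 to 105 CPM in fibroblast-like cells (7.05), from 2.98 to 89.9 CPM in macrophage-like cells (4.91) and from 9.48 to 224 CPM in B cell-like cells (4.46). Its annotated span, 84992690 to 85270566, overlaps its neighbours, and genes of this family are near-identical, so the split of reads among them is uncertain. Csprs, a related gene absent from the annotation, rose in fibroblast-like cells from 0.82 to 44.03 CPM (5.73) with the same limit.

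**Figure D4:**
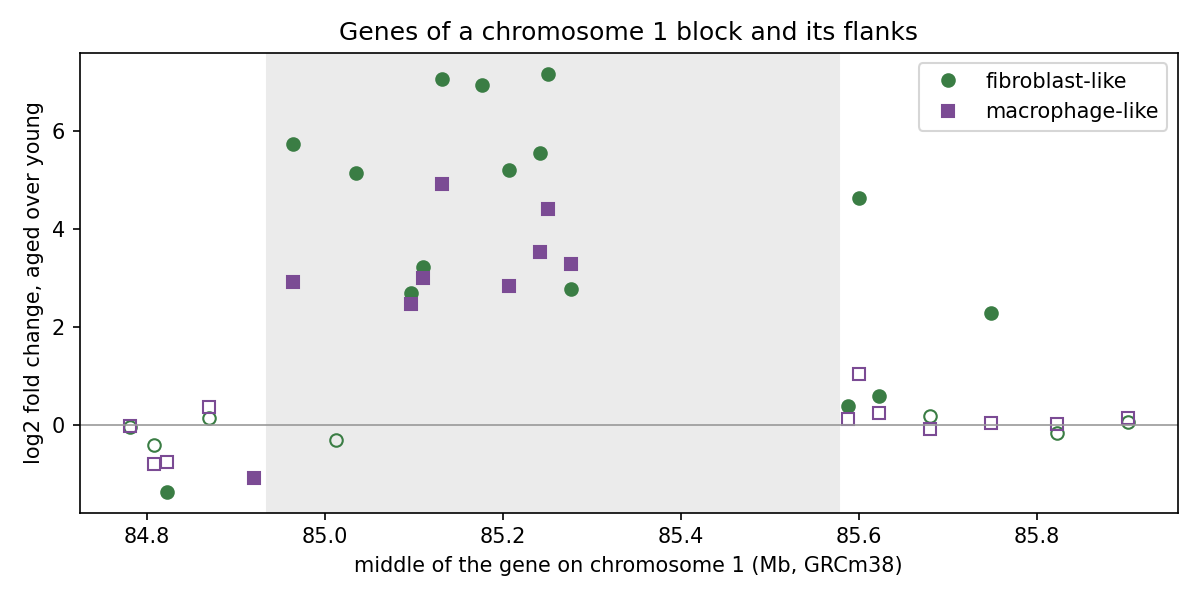
Log2 fold change, aged over young, of genes by position along chromosome 1 in Mb, in fibroblast-like and macrophage-like cells, with filled points for genes past adjusted p = 0.05 and a grey band for the block. Of the tested block genes 10 of 11 in fibroblast-like cells and 8 of 8 in macrophage-like cells rose.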

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

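The tests of the depth of aged replicate 2, of damaged barcodes, of preparation, of gene copies and of spread reads were chosen only after the results were seen, and the test of a shift between fibroblast clusters was written before its result. The results given first are those whose age effect differed between fibroblast-like and macrophage-like cells by the interaction test. Values are differences in log2 fold change, fibroblast minus macrophage.

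The age effect differed for 2731 genes. Lists with a higher value in fibroblast-like cells were MHC class I presentation (median 0.3984), interferon-stimulated genes (0.2582), senescence (0.4064), immediate early genes (0.1962) and alarmin transcripts (0.3809). The naive lymphocyte list (0.7701) and the 2 matrix lists, fibrillar collagen (0.8326) and basement membrane (0.5005), were of this kind too, although collagen transcripts in macrophage-like droplets are at the level that free RNA brings. Lists with a lower value in fibroblast-like cells were the unfolded protein response (-0.3239), resident macrophage (-0.3694), M2-type (-0.5037) and tubule transcripts (-1.042). Kap stood at 46.9 and 11.03 CPM in fibroblast-like and at 54.7 and 18.4 CPM in macrophage-like droplets, against 29770 CPM in young proximal tubule-like cells. Free RNA can likewise set the naive lymphocyte list in both classes, and the resident macrophage and M2-type lists in fibroblast-like droplets. All 12 list differences were lost with an estimated correlation (adjusted p = 0.474 to 0.595 with an estimated correlation). Among genes the difference was 2.10 for C4b, 2.27 for Cxcl12, 2.48 for Pltp, 1.32 for Apoe, 2.08 for C130026I21Rik and 3.33 for Csprs. It was -2.42 for Cd55, -5.05 for Cxcl13 and -0.67 for Hspa5.

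The fall of the collagen and matrix list in aged fibroblast-like cells came with a change in which clusters held the class. Within clusters 2 and 3 the list still fell, with a median log2 fold change of -0.58 and -0.546. For the cells of these clusters this argues against a shift between clusters as the whole cause. They held only 8.07% and 4.28% of the aged class, so how far a shift accounts for the fall over the whole class stays open. Without aged replicate 2, the shallowest library, the median was -0.9117, which argues against its depth. Clusters 1, 7 and 9, with too few cells in a library of the other age, were not tested alone. Cluster 5 held 51.5% of the aged class and had enough cells in each library, with 53 and 59 in the young libraries. It was not tested alone either, so whether the list fell within cluster 5 is not known. Age, any other difference between the mice and a difference in preparation may each account for what remains, and these were not tested apart.

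A set of 8 transcripts, mitochondrial or overlapping ribosomal RNA, was picked because each fell in at least 6 of the 7 classes. It includes the nuclear gene Lars2. Its mean log2 fold change over the classes was -0.942. In blood endothelial-like cells Lars2 and AY036118 did not pass (adjusted p = 0.22 and 0.28), nor did mt-Nd1 and mt-Nd4 in type 2 innate lymphoid-like cells (adjusted p = 0.15 and 0.22). The median over genes and classes was -0.885, and -0.881 with the stricter cell filter. That filter took the median mitochondrial share of the young libraries only from 2.69% and 2.67% to 2.62% and 2.6%, so damaged cells in the young libraries stay open as a cause. With it mt-Nd1 in blood endothelial-like cells went from a log2 fold change of -1.22 to -0.81, and mt-Nd4 from -1.50 to -1.13. The mean difference between the 2 libraries of an age was at most 0.305, under 0.471, so the genes did not split the libraries within an age to that extent. A difference in preparation between the young and the aged libraries cannot be told apart from age, since the labels give no batch.

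The chromosome 1 block may reflect a difference in gene copies between the mice, which would change each gene by a like factor in every class. Of 8 block genes tested in both fibroblast-like and macrophage-like cells 2 differed in their age effect, and Csprs, which is not among the 8, differed as well (3.33). C130026I21Rik did not pass in dendritic cell-like cells (log2 fold change 0.90). These values go against a like factor for those genes. Young levels of C130026I21Rik were 0.8 CPM in fibroblast-like and 2.98 CPM in macrophage-like cells, so low that reads of similar genes can set the factor, which leaves copy number open. Reads of 1 expressed gene spread over its near-identical neighbours would keep the neighbours in 1 ratio, but the ratio of C130026I21Rik to A530032D15Rik counts in aged libraries was 4.93 in fibroblast-like, 8.98 in macrophage-like and 2.45 in B cell-like cells. The highest was 3.668 times the lowest, which argues against it for this pair. A strain difference between the young and aged mice and an effect of age both stay open.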

How the results depend on the processing

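The fits within single clusters, without 1 cluster and with unnamed clusters counted in were chosen after the results were seen, and the other settings before. Counts within 1.5 times the reported count are taken as alike, as 93 of 133 were. The causes of the changes below were not tested, except that settings with fewer cells, libraries or genes have less power by construction.

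The DESeq2 test gave fewer genes than edgeR: 2599 in fibroblast-like, 979 in macrophage-like, 828 in blood endothelial-like, 147 in T cell-like, 64 in B cell-like, 129 in dendritic cell-like and 37 in type 2 innate lymphoid-like cells. With no filter on low counts B cell-like cells gave 304 genes and dendritic cell-like cells 396. Within fibroblast-like clusters 2 and 3 the counts were 751 and 378, within macrophage-like clusters 6 and 11 they were 735 and 354, and within blood endothelial-like clusters 14 and 16 they were 90 and 162, and within T cell-like clusters 4 and 12 they were 121 and 124. Leiden resolution 0.5 gave 90 genes in the blood endothelial-like class, and 351 of the 1360 genes called there by the reported fit and tested in both had the opposite sign. This is not a separate result from the fit in cluster 14. At that resolution the class had the same 38, 29, 232 and 565 cells per library as cluster 14. A cluster of 605 cells that scored best as blood endothelial stayed unnamed.

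Leaving out 1 library gave 3085 to 4572 genes in fibroblast-like and 1206 to 2567 in macrophage-like cells, the lowest without young replicate 1. It gave 1171 to 1822 in blood endothelial-like cells, the lowest without aged replicate 2, 111 to 394 in T cell-like cells, the lowest without aged replicate 2, and 1 to 153 in B cell-like cells, the lowest without young replicate 2. It gave 159 to 253 in dendritic cell-like cells and 49 to 164 in type 2 innate lymphoid-like cells, the lowest without aged replicate 2, and 1623 to 1993 genes in the interaction test, the lowest without aged replicate 1. The shares past the test numbered 2 to 9, the lowest without aged replicate 1 or 2, and the list calls 95 to 106. Without 1 library the cell cycle list in T cell-like cells had medians from -0.71 to 0.047 and the nuclear-encoded oxidative phosphorylation list there 0.076 to 0.24. The lipid-associated list in dendritic cell-like cells, not called in the reported fit, had -0.20 to 0.28. The test direction of all 3 turned without young replicate 1.

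The numbers of the replicates are not known to pair the samples. Deviations of replicate 1 correlated between the ages at -0.02 to 0.09, which cannot exclude a shared litter or day. The replicate block serves as a check only: with it 612 genes changed in T cell-like, 304 in B cell-like, 401 in dendritic cell-like and 79 in type 2 innate lymphoid-like cells, 6 of 16 shares passed and 104 lists were called. The shares of dendritic cell-like, plasma cell-like and proximal tubule-like cells lost their calls with it (edgeR adjusted p = 0.0503 for each). So did that of loop and distal tubule-like cells (0.083).

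As shares of immune cells 6 of the 10 classes tested passed, 5 rising and 1 falling. The mural cell-like share, which had not passed (log2 ratio 0.26), fell with the stricter cell filter (-0.82). With an estimated correlation 0 lists were called, and 61 without the genes under the free RNA limit, where the protease and complement lists in macrophage-like cells, not called in the reported fit (medians -0.29 and -0.07), rose (0.38 and 0.028). In single clusters values turned for Postn (0.0056, cluster 2), Il33 (0.19, cluster 3) and Col4a1 (-0.86, cluster 3) in fibroblast-like cells, for Cd74 (-0.47, cluster 6), Timd4 (0.37, cluster 11) and Retnla (0.085, cluster 11) in macrophage-like cells, and in blood endothelial-like cells for Igfbp3 (-0.19 in cluster 14 and at Leiden resolution 0.5, -0.22 in cluster 16), Cd36 (0.16), Esm1 (-0.16) and Cd74 (-0.23) in cluster 16. Gzmm in T cell-like cells turned to 1.51 with doublets kept, 1.44 with the stricter cell filter, 1.47 at Leiden resolution 0.5, 1.48 at resolution 2 and 1.48 with cluster 10. Values there also turned for Cd4 (1.85), Cd8a (-0.078) and Cd8b1 (-0.083) in cluster 4 and for Ccl5 (-0.46) and Cd8a (-1.59) in cluster 12, none passing, and in dendritic cell-like cells for Apol7c without cluster 31 (-2.03, adjusted p = 0.72). Over all settings, named genes past the test kept their direction and call in 1625 comparisons and lost the call in 112, lists in 489 and 154 and shares in 96 and 25. The direction of called results turned in 21 comparisons of genes and 2 of lists.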

Other observations

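The comparisons of this part were chosen after the results were seen, apart from the gene tests themselves, which were planned.

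Many changes were shared by several classes. In at least 4 of the 7 tested classes 38 genes rose without falling in another, and 53 fell without rising in another. In all 7 classes 5 genes fell, the matrix gene Sparc, the mitochondrial genes mt-Nd2, mt-Nd3 and mt-Rnr1 and the ribosomal RNA transcript Gm42418. Genes that rose in 5 classes included the ribosomal protein genes Rps7, Rps10 and Rpl24, the cold-inducible RNA-binding protein gene Cirbp, the methyltransferase partner Trmt112 and the chemokine Ccl8. Outside macrophage-like cells the aged level of Ccl8 in these classes was 51.4 to 75.6 CPM, against 7622 CPM in macrophage-like cells. Free RNA can bring such a low level, and how much of the rise there it accounts for was not tested. Likewise Sparc stood at 73.3 to 115 CPM in the young immune classes tested for genes against 9876 CPM in fibroblast-like cells, but at 3824 CPM in young and 2095 CPM in aged blood endothelial-like cells, which is above the level of free RNA. The long non-coding RNA Snhg11, known from neural tissue, rose in fibroblast-like cells from 2.92 to 49.0 CPM (log2 fold change 4.07).

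Whole-library levels of Igkc and Kap moved in the direction of the shares of plasma cell-like and tubule-like cells. Igkc stood at 38.6 and 56.9 CPM in the young libraries and at 21434 and 35893 CPM in the aged libraries, where plasma cell-like cells were found. Kap, a tubule transcript, stood at 1804 and 1717 CPM in the young and at 210 and 565 CPM in the aged libraries. The haemoglobin gene Hbb-bs stood at 37.0 and 132 CPM in the young and at 0.59 and 2.15 CPM in the aged libraries. No erythroid class was named, and Hbb-bs was among the leading genes of the mast cell-like class at Leiden resolution 2.

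Of the genes tested, 37 are absent from the annotation used for coordinates, and of these 10 rose and 8 fell in at least 1 class.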
